A study of Mus musculus with 10 samples.

How the data were processed

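RNA sequencing was carried out on adult mouse heart muscle cells (cardiomyocytes) isolated by Langendorff perfusion, in which digestive enzymes are passed through the coronary vessels of the excised heart. The 10 libraries came from FVB/N mice, 5 wildtype and 5 carrying the Epac1-PLN transgene. Each genotype held 2 males and 3 females. Per the labels, Epac1-PLN is a fluorescence (FRET) sensor made by heart cells. Its name joins Epac1, a cAMP-binding protein, and phospholamban, the regulator of the calcium pump of the sarcoplasmic reticulum; its sequence is not given in the sources used here. Each library is labelled as a separate biological replicate. Libraries were made from total RNA with the TruSeq RNA kit and sequenced on a HiSeq2000, per the labels' protocols.

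The authors deposited a table of raw read counts per Ensembl gene and a second table of the same genes. The values of the second table are a normalized signal, each deposited count divided by the size factor of its library. The size factors recovered from the deposited tables equalled DESeq median-of-ratios factors recomputed from the counts, with a largest relative difference of 9.86e-15. The submitters' processing notes name CASAVA 1.8.2, FastQC 0.10.0, STAR 2.3.0, HTSeq 0.5.4, DESeq and DESeq2, and the mm10 genome build. Their settings, the annotation version and the use of strand in counting are not given in the sources used here. Reads of a gene and of a gene that overlaps it on the other strand may therefore share a count, and overlapping genes are named in the text. The table held 38355 genes, of which 470 had no symbol and 0 lay on the mitochondrial genome, so no mitochondrial share was computed. Coordinates are those of the deposited table. Of the gene identifiers, 36602 were also in GENCODE M21, and 25481 of these had identical coordinates there.

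Library totals ranged from 10632224 to 20983754 counts. The 2 groups did not differ in total by an exact 2-sided permutation test (p = 0.183), and no 2 libraries of 1 group were as close as sampling noise alone would make them (chi-square per degree of freedom 7.55 to 30.3 over 20 pairs). The sources used here name no molecular identifiers, so counting intervals cover counting error only.

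Genes were kept with the filterByExpr rule of edgeR 4.0.16 on genotype, which left 12629 genes. Counts were scaled by TMM factors and tested with edgeR's quasi-likelihood F test with robust dispersions in R 4.3.3. The model held sex and genotype, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. A called gene is one past this threshold. The sex coefficient came from the same model, and the genotype-by-sex term from a model with that term added. Standard errors were obtained as the absolute log2 fold change divided by the square root of F. Levels are edgeR's CPM values with TMM factors, as mean ± SD.

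The 36 gene lists covered the sensor's parent genes, cAMP signalling, calcium handling, ion channels, contraction, metabolism, stress, the clock, sex-linked genes and markers of other cell types. The list of the sensor's parent genes also held the myosin genes Myh6 and Myh7. Of these, 32 had at least 3 tested members. The lists not tested were the mitochondrially encoded mRNAs (0 tested members), the neutrophil markers (1, at a log2 fold change of 0.56), the lymphocyte markers (1, at -0.09) and the adipocyte markers (2, with a median of 0.06). Lists were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. Per-library values were compared by exact permutation of the 10 labels, over 41 quantities. Chi-square, correlation and library checks used the same counts.

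Genes were named by a rule. It took the sensor's parent genes and 12 cardiac genes in every case. It added, per direction of the genotype effect, the 8 called genes with the largest change, a mean of at least 1 CPM and no overlap between the groups, and the 4 with the smallest p. It also took up to 4 members of each list with the smallest p. For sex and for the genotype-by-sex term it took the 5 smallest p, for sex per direction. A few single-gene results are left out because they were withheld for evaluation. The design, the rule, the lists and the main alternatives were fixed before the data were examined. The alternatives were other normalizations, DESeq2 1.42.0, limma-voom with and without quality weights, other count filters, other covariates including 1 surrogate variable from sva 3.50.0 and a replicate block, females alone, and each library left out in turn. A correction for GC content and transcript length and a thinning to the smallest library were added after seeing the data. So were a removal of ribosomal-RNA-like genes, list tests without Rapgef3 and an estimated correlation without 1 library.

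The tests were checked on simulated counts with the means, dispersions and library sizes of these samples, in which 12553 genes passed the filter. For the genotype comparison, the quasi-likelihood test called 42.4% of genes changed by a log2 fold change of 0.5, 84.6% of those changed by 1 and 98.5% of those changed by 2. It called 8 of 12355 unchanged genes. The list test called the 1 list that had been shifted and 0 lists sharing no gene with it. These counts were simulated without correlation between genes, so this does not test how camera fares on correlated lists, and other splits of the real libraries called a median of 9 lists.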

Results

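Transcripts of adult cardiomyocytes were counted in 5 wildtype and 5 Epac1-PLN transgenic mice of the FVB/N strain. The design asks which genes change in heart muscle cells that carry the sensor, named after the cAMP-binding protein Epac1 and phospholamban. Totals were 20983754, 13721694, 18421567, 15522130 and 13266303 counts in wildtype replicates 1 to 5. They were 10632224, 15020169, 15959196, 14484564 and 12290526 counts in Epac1-PLN replicates 1 to 5. The labels gave wildtype replicates 1 and 2 and Epac1-PLN replicates 1 and 5 as males, and the other libraries as females. Xist, the RNA that silences an X chromosome, was at 73.7 to 133 CPM in the 6 female libraries and at 0 to 0.428 CPM in the 4 male libraries. The Y-linked gene Ddx3y was at 94.7 to 112 CPM in the males and at most 0.0781 CPM in the females. Every library thus matched its labelled sex.

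The sensor's parent genes gave the first check of the genotype labels. Reads counted at Rapgef3, the gene for Epac1 (ENSMUSG00000022469, chromosome 15, 97744770 to 97767972), rose from 12.8 ± 2.14 CPM in wildtype to 1507 ± 197 CPM in Epac1-PLN cells (SD, n = 5 per group). This is a 118-fold difference, with a log2 fold change of 6.89 ± 0.15 (SE) and an adjusted p of 3.28e-11 by edgeR's quasi-likelihood test. The 5 Epac1-PLN libraries held 13387 to 27103 Rapgef3 counts and the wildtype libraries 146 to 284. Counts per gene do not separate reads of the transgene from reads of the endogenous gene, and the antisense genes Rapgef3os1 and Rapgef3os2 overlap this locus. Pln, the gene for phospholamban (ENSMUSG00000038583, chromosome 10, 53337686 to 53345999), was not called. It stood at 10249 ± 1428 CPM in Epac1-PLN cells and 11105 ± 1292 CPM in wildtype, with a log2 fold change of -0.12 and a 95% interval of -0.37 to 0.14. It overlaps Cep85l and Gm47644. Myh6 and Myh7, the heavy chains of cardiac myosin, were not called either (log2 fold changes 0.14 and 0.08).

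**Figure D1:**
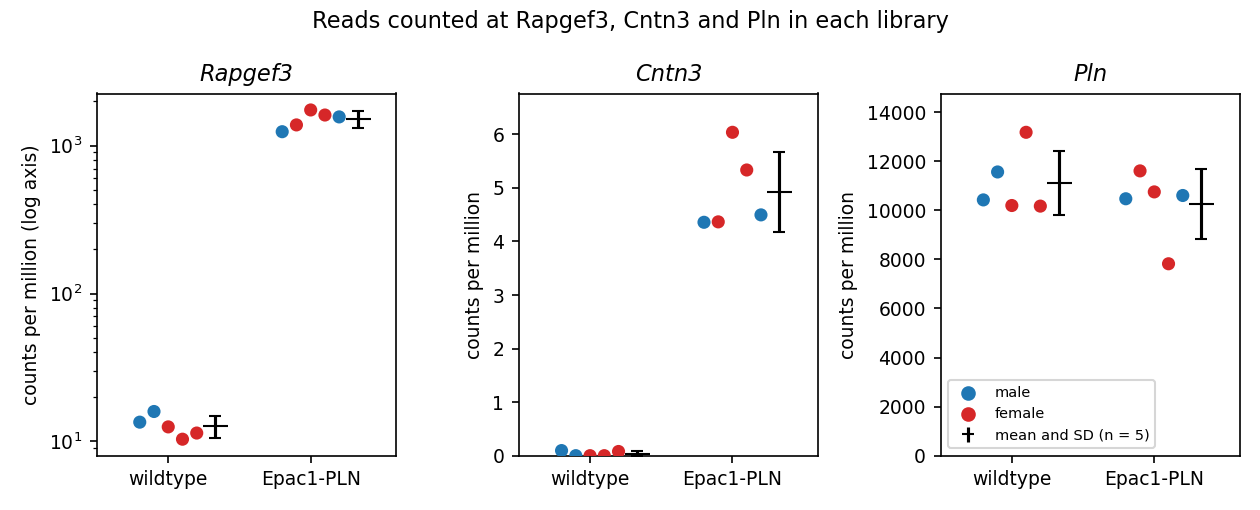
CPM in each library at Rapgef3 (log axis), Cntn3 and Pln (linear axes), with points coloured by sex and bars giving the mean and SD of 5 libraries. All 5 Epac1-PLN libraries lie above all 5 wildtype libraries for Rapgef3 and Cntn3, while the groups overlap for Pln.

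The second gene of this size was Cntn3, which encodes contactin 3, a cell adhesion protein known from neurons (ENSMUSG00000030075, chromosome 6, 102163306 to 102464667). It was close to absent from wildtype cells and present in all 5 Epac1-PLN libraries. It rose from 0.0347 ± 0.0478 to 4.92 ± 0.746 CPM (adjusted p = 2.29e-06, edgeR). The Epac1-PLN libraries held 47 to 94 Cntn3 counts each and the wildtype libraries 0 to 2 each. Over the groups these were 340 and 3 counts, a depth-corrected ratio of 136 with an exact binomial 95% counting interval of 46.1 to 662.

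Across the transcriptome the response was small. Of 12629 tested genes, 81 changed with genotype, 56 higher and 25 lower in Epac1-PLN cells, with a median absolute log2 fold change of 0.58. Of these, 17 changed by more than 2-fold, 14 upward and 3 downward. Without overlap between the groups were 64 of the called genes, and 347 of all tested genes against 100.2 expected by chance (0.794%). The count depended on single libraries. It was 14 without wildtype replicate 1, 44 without wildtype replicate 2, 41 without each of wildtype replicates 3, 4 and 5, 46 without Epac1-PLN replicate 1, 20 without Epac1-PLN replicate 3 and 39 without Epac1-PLN replicate 5.

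**Figure D2:**
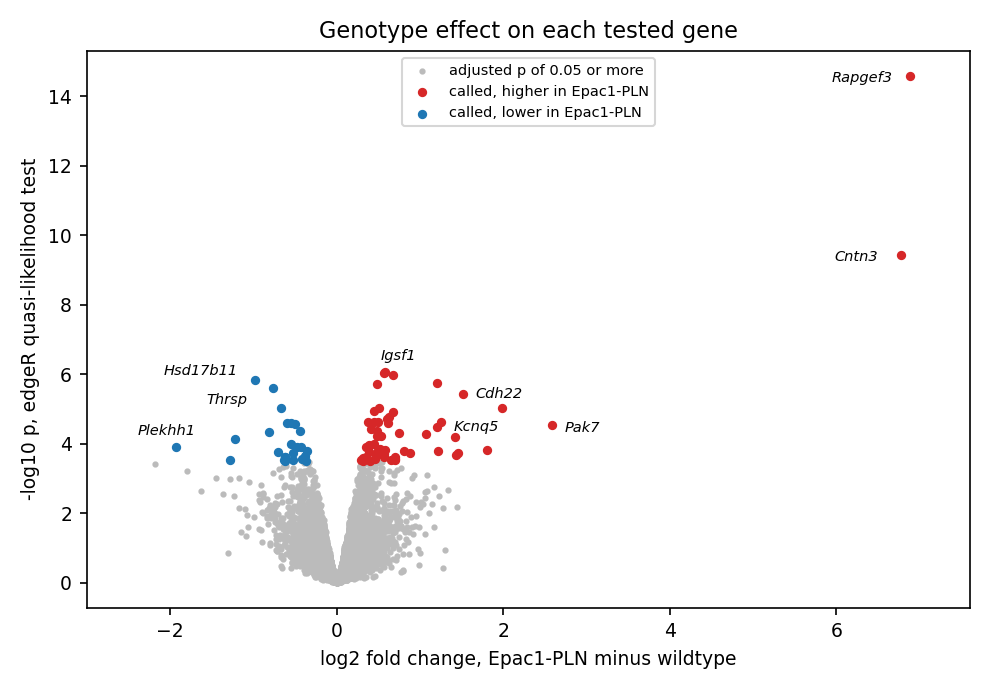
Log2 fold change (Epac1-PLN minus wildtype) against -log10 p from edgeR's quasi-likelihood test for the 12629 tested genes, with called genes in red (56 higher) and blue (25 lower). Rapgef3 and Cntn3 stand apart from all other genes, with log2 fold changes of 6.89 and 6.77.

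Several of the genes that rose were scarce in wildtype cells. Pak7, a p21-activated kinase, rose from 0.344 ± 0.104 to 2.10 ± 1.33 CPM (log2 fold change 2.59 ± 0.41 SE). Cdh22, a cadherin, rose from 1.76 ± 0.594 to 5.02 ± 0.453 CPM (log2 fold change 1.51 ± 0.20). The potassium channel gene Kcnq5 rose by 1.26 ± 0.20 and the phosphatase gene Dusp26 by 1.22 ± 0.23 on the log2 scale. Rp1, known from photoreceptors, rose from 0.605 ± 0.338 to 2.17 ± 0.560 CPM. The transcript 4930529M08Rik rose by 1.42 ± 0.25, but overlaps Crnkl1, and Kcnq5 overlaps Gm26580. More abundant genes rose by less. Atp6v0a1, a subunit of the vacuolar proton pump, rose from a mean of 103 to 153 CPM (log2 fold change 0.57 ± 0.06), and the membrane protein gene Igsf1 from 35.8 ± 8.33 to 53.8 ± 12.7 CPM (0.58 ± 0.07). Adjusted p-values (edgeR) of these genes ranged from 0.00261 for Atp6v0a1 to 0.0414 for Dusp26.

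Among the genes that fell, Hsd17b11, a dehydrogenase found on lipid droplets, had the smallest p. It fell from 48.7 ± 5.80 to 24.7 ± 4.12 CPM (log2 fold change -0.98 ± 0.12 SE, adjusted p = 0.0030, edgeR). Thrsp, a regulator of fat synthesis, fell from 95.4 ± 16.6 to 55.9 ± 7.74 CPM (-0.77 ± 0.10). The mitochondrial carrier gene Slc25a34 fell from 361 ± 61.6 to 236 ± 15.7 CPM (-0.60 ± 0.09). Prps2, an enzyme that makes the ribose precursor of nucleotides, fell by 0.67 ± 0.10 and the matrix protein gene Emilin2 by 1.22 ± 0.20 on the log2 scale. Lrp11 and the helicase gene Mov10 fell by 0.62 each, but were not called in 15 of 28 alternatives each. Plekhh1 (-1.93 ± 0.36) and Rabep2 (-0.63 ± 0.13) also fell, but overlap Pigh and Atp2a1. They were not called in 8 and 20 of 28 alternatives.

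The fatty acid oxidation genes had the smallest camera p after the list of the sensor's parent genes. Of 31 measured members, 30 lay lower in Epac1-PLN cells, with a median log2 fold change of -0.22. The list fell by camera (adjusted p = 1.30e-16), but its adjusted p was 0.353 with an estimated correlation and 0.0682 by fry. Over all genes 1 member fell, Cpt1a, a carnitine palmitoyltransferase that feeds fatty acids into mitochondria (34.8 ± 3.01 to 23.8 ± 2.89 CPM, log2 fold change -0.55 ± 0.09, adjusted p = 0.0135, edgeR). Adjusted over the list alone, 17 members passed, all lower, and 8 to 20 passed when each library was left out in turn. They included Plin5, a lipid droplet protein (-0.39), the acyl-CoA thioesterase gene Acot2 (-0.69), the uncoupling protein gene Ucp3 (-1.05) and Acsl1, which activates long fatty acids (-0.27). Per library, the mean level of the list was 8.59 ± 0.112 log2 CPM in wildtype and 8.27 ± 0.132 log2 CPM in Epac1-PLN cells, and all 5 Epac1-PLN libraries lay below all 5 wildtype libraries. The exact 2-sided permutation p was 0.00794, the smallest possible with 5 against 5 libraries, and 0.0813 after adjustment over 41 quantities. Epac1-PLN replicate 4 had the lowest level, 8.04, and without it 27 of 31 members lay lower.

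**Figure D3:**
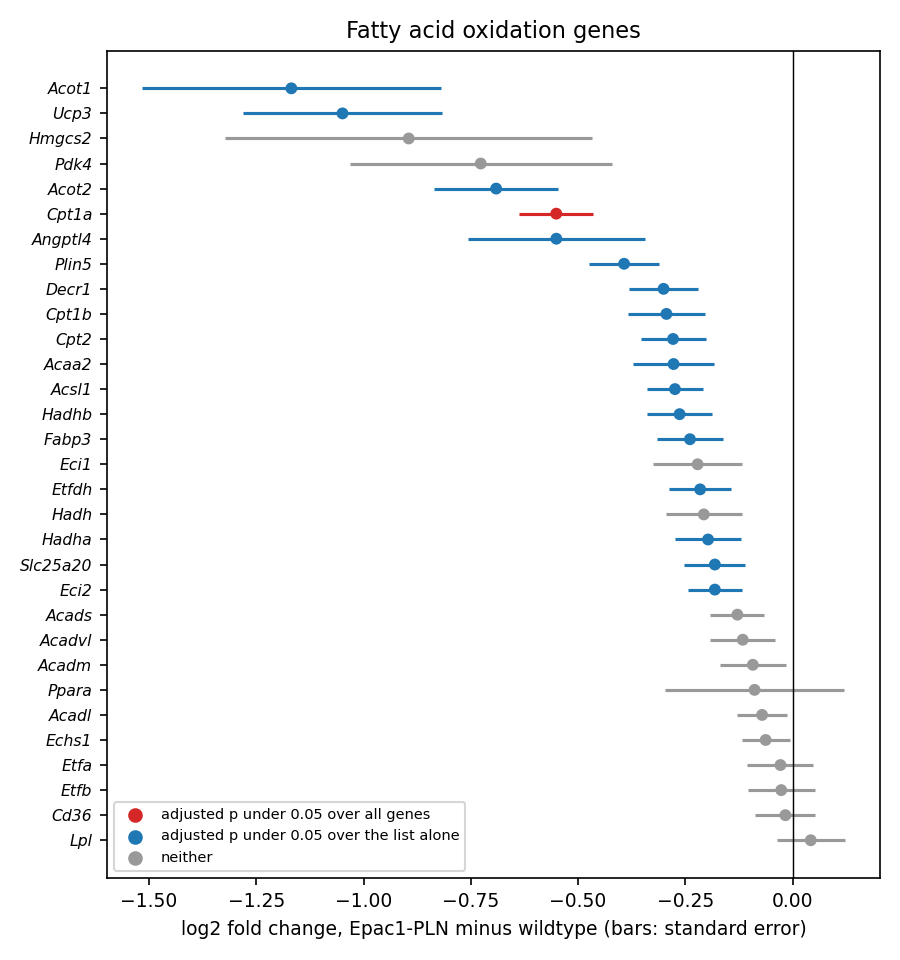
Log2 fold change (Epac1-PLN minus wildtype) of the 31 measured fatty acid oxidation genes, with bars giving the standard error and colours the call. With TMM scaling 30 of the 31 genes lie below 0, and Lpl alone lies above it.

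Other metabolic lists moved little. Nuclear-encoded oxidative phosphorylation genes were lower in 38 of 46 members with a median of -0.05. That list was called by camera (adjusted p = 0.0473), with an adjusted p of 0.975 with an estimated correlation, and 0 members changed over all genes or adjusted over the list alone. Glycolysis genes (median 0.00 over 24 members) and cytosolic ribosomal protein genes (median 0.01 over 40) were not called. In the oxidative stress list, which was not called, Nqo1, a quinone reductase, fell from 118 ± 15.3 to 85.1 ± 4.41 CPM (adjusted p = 0.0371, edgeR). The catalase gene Cat passed as well when adjusted over the list alone (-0.24).

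In the cAMP pathway, the receptors, cyclases and phosphodiesterases did not pass as groups. Of 16 beta-adrenergic receptor and G protein genes, 8 adenylyl cyclases, 18 phosphodiesterases and 16 CREB target genes, 0 changed over all genes. Adrb1, the main cardiac beta-adrenergic receptor, was at 21.4 ± 4.18 CPM in Epac1-PLN cells against 28.1 ± 4.53 CPM in wildtype (log2 fold change -0.40 ± 0.14, adjusted p = 0.266, edgeR). Pde2a, Pde3a and Pde4b had log2 fold changes of 0.08, -0.11 and -0.18. Pde4d (ENSMUSG00000021699), whose symbol the table also gives to a neighbouring gene, stood at 31.0 ± 3.81 against 30.9 ± 6.32 CPM. Of the phosphodiesterases 1 passed when adjusted over the list alone, Pde11a, at 1.01 CPM in Epac1-PLN cells against 4.29 CPM in wildtype (-2.18 ± 0.44).

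The list of cAMP effectors and anchoring proteins rose by camera (adjusted p = 4.85e-11), with an adjusted p of 0.0813 with an estimated correlation. Its members went both ways, 12 higher and 10 lower, and without Rapgef3 its adjusted p was 0.303. Besides Rapgef3, Bves, a cAMP-binding Popeye protein, rose by 0.30 ± 0.06 on the log2 scale (adjusted p = 0.0496, edgeR). Bves was not called in 20 of 28 alternatives. Popdc3, another Popeye protein gene, passed as higher (0.38) and the anchoring protein gene Akap7 as lower (-0.39) when adjusted over the list alone. The list of the sensor's parent genes, which also held Myh6 and Myh7, rose too (adjusted p = 0.000179 with an estimated correlation). Its adjusted p without Rapgef3 was 0.786.

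Calcium handling and ion channel lists were not called, but held single called genes. Srl, which encodes sarcalumenin, a calcium-binding protein of the sarcoplasmic reticulum, rose from 1609 ± 101 to 2137 ± 139 CPM (log2 fold change 0.41 ± 0.07, adjusted p = 0.0174, edgeR). Adjusted over the list alone, 4 of 29 calcium handling genes passed as higher, Srl, Slc8a1 (0.37), Atp2b1 (0.24) and Hrc (0.25), and Cacnb2 as lower (-0.31). Atp2a2, the calcium pump that phospholamban regulates, and Ryr2, the calcium release channel, had log2 fold changes of -0.01 ± 0.09 and 0.09 ± 0.10. Of 29 action potential channel genes, Cacna1g, a T-type calcium channel, rose by 0.66 ± 0.13 (adjusted p = 0.0496, edgeR) and Kcnv2, a silent potassium channel subunit, fell by 0.70 ± 0.13 (adjusted p = 0.0414, edgeR). They were not called in 16 and 10 of 28 alternatives. Adjusted over the list alone, 5 passed as higher and 2 as lower, among them Kcnip2, a partner of the transient outward current channel (-0.33). Of the channel genes 21 lay higher. Their mean level per library was 5.20 ± 0.0365 log2 CPM in wildtype and 5.29 ± 0.0379 log2 CPM in Epac1-PLN cells, without overlap. The exact permutation p was 0.00794, the smallest possible, and 0.0813 adjusted over 41 quantities, as for fatty acid oxidation, cAMP effectors and the sensor's parent genes.

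Heart failure markers gave little signal. Nppa stood at a mean of 40.6 CPM in Epac1-PLN cells against 41.8 CPM in wildtype, and Nppb at 498 ± 58.8 against 456 ± 116 CPM. The hypertrophy and fetal gene list was called higher by camera (16 of 21 members, median 0.22, adjusted p = 0.0244), with an adjusted p of 0.378 with an estimated correlation. In it 0 members changed over all genes or adjusted over the list alone. Of 24 sarcomere genes 0 were called (median 0.04). Heat shock genes rose by camera (14 of 16 higher, median 0.21, adjusted p = 0.000758), with an adjusted p of 0.644 with an estimated correlation. Over all genes 1 of them rose, the chaperone gene Hsph1 (138 ± 24.2 to 240 ± 51.5 CPM, adjusted p = 0.0413, edgeR). Its levels overlapped between the groups, and it was not called in 9 of 28 alternatives. Hsp90aa1 passed too when adjusted over the list alone (0.67). Unfolded protein response genes were called higher (21 of 24, median 0.13, adjusted p = 0.0374), with an adjusted p of 0.975 with an estimated correlation. Over all genes 0 of them changed, and adjusted over the list alone Atf6 passed (0.36).

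The clock list was not called (adjusted p = 0.887) and 0 of its 19 members changed over all genes. Of these, 5 passed when adjusted over the list alone. The repressor genes Cry1 (0.73), Cry2 (0.43) and Nfil3 (0.70) were higher, and Bhlhe41 (-0.42) and Gm129 (-0.46) lower. The immediate early and isolation stress genes (median 0.16 over 26 members, adjusted p = 0.0904) and the interferon-stimulated genes (0.12 over 21) were not called.

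The lists of other cell types showed 0 called members and were not called with genotype. Median log2 fold changes were -0.01 for adult cardiomyocyte, -0.02 for fibroblast, 0.13 for endothelial, 0.23 for macrophage and leukocyte, and -0.05 for smooth muscle and pericyte markers. They were 0.19 for atrial myocyte, 0.04 for Schwann and neuronal, 0.36 for mesothelial and -0.37 for erythroid markers. Of all these markers 1 passed adjusted over the list alone, the noradrenaline enzyme gene Dbh (-0.71). Extracellular matrix and cell cycle genes had medians of 0.02 each. Epac1-PLN replicate 4 stood apart, with the lowest median Spearman correlation with the other libraries (0.983). Without it, 99 genes and 11 lists were called with genotype. Of these lists 6 were lower, among them fibroblast, extracellular matrix, cell cycle and endothelial genes, and 2 of 32 lists were called with an estimated correlation. The endothelial list thereby turned to the opposite direction (camera adjusted p = 0.0260, and adjusted p = 0.704 with an estimated correlation).

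The sexes differed as well. With genotype in the model, 43 genes changed with sex, 19 higher and 24 lower in females, and 9 of them lie on the X chromosome. This count was 18 and 20 without wildtype replicates 1 and 2, 19 without Epac1-PLN replicate 1, and 81 and 93 without Epac1-PLN replicates 4 and 5. Besides Xist, the X-linked genes Kdm5c (75.3 ± 5.76 CPM in 6 females against 44.0 ± 5.88 CPM in 4 males), Kdm6a (log2 fold change 0.96 ± 0.08), Eif2s3x (14.3 ± 2.15 against 7.05 ± 0.348 CPM) and Ddx3x (316 ± 36.0 against 193 ± 12.6 CPM) were higher in females. Of the 9 genes of the sex-linked list 4 passed the filter, all of them X-linked, and all 4 were higher in females. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, found in the 4 males only, did not pass the filter, which was set on genotype. They are therefore missing from this list's test and from the 24 genes lower in females. Among the genes lower in females, C7, a complement component, was at 0.731 ± 0.212 CPM in females against 9.80 ± 3.16 CPM in males (log2 fold change -3.70 ± 0.25 SE, adjusted p = 1.19e-05, edgeR). Penk, the enkephalin precursor, was at 1.18 ± 0.32 against 5.65 ± 1.53 CPM (-2.24 ± 0.22) and Dpep1, a dipeptidase, at 4.75 ± 1.21 against 14.8 ± 2.23 CPM (-1.64 ± 0.14). Hsd11b1, which regenerates active glucocorticoid, was lower by -1.78 ± 0.15, and Mgst1, a glutathione transferase, by -1.11 ± 0.11.

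Groups of genes also went with sex, though only the sex-linked list kept its call with an estimated correlation (adjusted p = 3.14e-05). Fibroblast markers were lower in females in 12 of 14 members (median -0.16, adjusted p = 0.456 with an estimated correlation). Over all genes 2 of them fell, Dpep1 and Dcn, and 3 adjusted over the list alone. Interferon-stimulated genes were lower in all 21 members (median -0.56, adjusted p = 0.456 with an estimated correlation), with 0 called over all genes and 6 adjusted over the list alone. Macrophage and endothelial markers were lower in 15 of 17 and 14 of 15 members (adjusted p = 0.788 each with an estimated correlation). Immediate early genes and CREB target genes were higher in 24 of 26 and 13 of 16 members (adjusted p = 0.456 each with an estimated correlation), of which 1 and 4 passed adjusted over the list alone. The remaining lists called with sex by camera were heat shock and unfolded protein response genes, higher in females, and oxidative phosphorylation genes, lower in females (adjusted p = 0.788 each with an estimated correlation).

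Whether the genotype effect differed between the sexes was tested with the genotype-by-sex term. By edgeR's quasi-likelihood test 0 of 12629 genes passed, and 474 had an unadjusted p under 0.05. DESeq2 called 1 gene, Cyp26b1, which degrades retinoic acid (adjusted p = 0.0140, DESeq2), limma-voom called 0 with or without quality weights, and edgeR without a low-count filter called 164. The smallest p-values were those of Aass, St8sia4, Cyp26b1, Tbx18 and Cish, with log2 differences of the genotype effect (females minus males) of -2.16, 1.34, -3.02, 1.24 and 0.98. Cyp26b1 averaged 14.8 CPM in Epac1-PLN males, 2.37 CPM in wildtype males, 2.37 CPM in Epac1-PLN females and 2.94 CPM in wildtype females. With 2 males per genotype, such values rest on few animals. Without Epac1-PLN replicate 1, a male, 1 Epac1-PLN male is left, so the spread in that fit comes from the other groups. There the interferon-responsive genes Igtp and Irgm2 had log2 differences of -2.59 and -2.02, given as effect sizes only.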

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

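The chance splits of the samples and the clock adjustment were planned before their results were seen. The tests of GC content, depth, cardiomyocyte share, Epac1-PLN replicate 4, neighbouring genes, insertion and shared sequence were chosen after the result was seen.

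In 5 of 142 groups of 5 libraries, 1 library lay far from the other 4, where chance alone gives about 1 in 20, or 7.1. The gap to the nearest library took up a share of 0.731 of the group's range for Gm23935, 0.843 for Gm15564 and 0.906 for the percent of counts on genes without a symbol, each time with Epac1-PLN replicate 4 as the highest library (40.6 CPM, 114 CPM and 0.0413%). The mean log2 CPM of the macrophage and leukocyte markers was lowest in wildtype replicate 3 (0.931 against 1.71 to 1.92 in the others, a share of 0.787). That of the atrial myocyte markers was highest in wildtype replicate 1 (2.97 against 2.14 to 2.33, a share of 0.779).

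The number of genes called with genotype was weighed first. Of 100 of the 126 splits of the 10 libraries into sets of 5, 2 gave at least as many genes as the real 81, the real split included. So large a count was rare among the splits. They were drawn without balancing the sexes, which the real split does, and sets that mix the genotypes hold the genotype effect in their spread. Both can lower the counts of other splits, so this share does not exclude chance. The other was a split that called 200 genes. It placed all 4 males with Epac1-PLN replicate 4, so with sex in the model it set that library against the other females, which points to a structure of the samples. A trend on GC content or transcript length is argued against, since 79 of the 81 genes were still called after its removal. After thinning to the smallest library, 78 genes kept at least 80% of their log2 fold change. Thinning leaves the expected scaled fold change as it was, so this cannot decide whether depth had a part. At the thinned totals 59 of the 81 genes were still called, but thinning also removes reads. Chance, depth, the transgene, and any difference in how the animals were bred or kept stay open.

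With sex, 43 genes were called, against at most 25 in the other splits, and 1 of 100 splits, the real one, reached that count. This is the smallest share that 100 splits can give, and they were not balanced for genotype. Chance is thus argued against as the whole source of this count, but not excluded. For the lists the splits do not argue against chance. At least the real 7 lists were called with genotype in 81 of 100 splits (highest other 20), and at least the real 10 with sex in 58 of 100 (highest other 19).

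The lower level of the fatty acid oxidation genes was weighed second. Camera gave this list as small a p in 4 of 100 splits, the real one included (8.11e-18, against a lowest of 1.81e-32 in the others). This share is below the 5 in 100 set beforehand for this list taken alone, but other splits gave smaller p-values. The list was also singled out among 32 lists, and 61 of the splits called it, so chance cannot be excluded. Epac1-PLN replicate 4 alone does not carry it, since the median without that library was -0.17. For the time of isolation, 104% of the genotype difference was left after adjustment for a clock phase score (94.5% to 115% with each library left out). The adjustment held no sex term, though the score went partly with sex. It was 1.04, 1.89, -0.318 and 0.948 in the males and -1.55 to 0.0556 in the females. The score genes Dbp, Npas2, Gm129 and Bhlhe41 passed with sex, adjusted over the clock list alone. The fitted slope can thus reflect sex, so this cannot decide whether the time of isolation had a part. The clock phase score itself was -0.425 ± 0.922 in Epac1-PLN and 0.425 ± 1.05 in wildtype libraries (exact permutation p = 0.206). Of 19 clock genes 5 passed adjusted over the list alone, 3 higher and 2 lower. Cry1 and Nfil3 (higher) and Bhlhe41 and Gm129 (lower) are part of the score and moved in the direction of its lower value. Cry2 (higher) is not in the score, so clock genes outside the score were not tested. Fewer cardiomyocytes among the cells stay open. The median of the cardiomyocyte markers was -0.01 (-0.007557 unrounded), with 6 higher and 9 lower. The gap of 0.214 to the oxidation genes is within 2 SD of the single markers (SD 0.158), which is not the error of their median. Over all alternatives the marker median stayed between -0.05 and -0.00013, and that of the oxidation genes between -0.30 and -0.17. Of the other markers, 15 of 17 macrophage and 13 of 15 endothelial genes lay higher. The macrophage level was 1.64 ± 0.405 log2 CPM in wildtype and 1.79 ± 0.485 in Epac1-PLN libraries (exact permutation p = 0.635). It was lowest in wildtype replicate 3, at 0.931 against 1.71 to 1.92 in the other wildtype libraries. The endothelial part rests on Epac1-PLN replicate 4, since without it that list lay lower (camera adjusted p = 0.0260, but adjusted p = 0.704 with an estimated correlation), while 27 of 31 oxidation genes still lay lower. A response of lipid metabolism to the sensor may remain as a hypothesis, together with feeding or housing of the animals, which were not tested.

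The rise of Cntn3 was weighed last. A change spread over its chromosome region is argued against only where genes were tested. The 13 tested genes within 5 Mb had a median absolute log2 fold change of 0.117, against 0.104 over all tested genes. The nearest, Pdzrn3, ends at 101377897, and the first at higher coordinates than Cntn3, Trnt1, starts at 106769120. A change confined to the stretch between these 2 genes could not be seen. Reads of the Rapgef3 or Pln part of the sensor are argued against for the mouse sequences, since 0 stretches of 25 bases outside simple repeats were shared. The first form of this test had asked for any shared stretch and found 2, both from a CA repeat. The sensor's fluorescent proteins and vector were not analysed here. An insertion of the transgene in or next to Cntn3 may be a source, and 0 of the 13 neighbours were called, but counts per gene hold no read positions, so it cannot be told apart from a response to the sensor.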

How the results depend on the processing

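The count of genes called with genotype was 81, and it ranged from 14 to 103 when each library was left out in turn. Under the other normalizations, plain limma-voom, the test without robust dispersions, the stricter count filter, removal of the 20 most abundant genes and the deposited normalized values it stayed between 64 and 88. It was 265 with DESeq2, 273 with limma-voom and quality weights, and 498 without a low-count filter, of which 494 had been tested before. It was 37 without sex as covariate, 25 with 1 surrogate variable, and 4 in females alone with fewer samples. It was 51 with an absolute log2 fold change above 0.5 and 185 at an adjusted p of 0.1. Of the alternatives chosen after seeing the data, removing the trend on GC content and length gave 146 genes, while thinning and removing ribosomal-RNA-like genes gave 66 and 76. With a replicate block 2 genes were called, Rapgef3 and Cntn3. Libraries of the same number correlated at -0.3 to 0.352 once genotype was removed, and at -0.344 to 0.348 once sex was removed too. With genotype removed, 1 of 5 wildtype libraries correlated best with its own number. This gave no sign that the numbers pair the samples, though 5 pairs cannot settle it.

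With sex, 43 genes were called, and 158 with DESeq2, 212 with limma-voom and quality weights, 521 without a low-count filter, 3 with a replicate block and 77 at an adjusted p of 0.1. Leaving out each library gave 18 to 93, the lowest without wildtype replicate 1 and the highest without Epac1-PLN replicate 5. For the genotype-by-sex term the count of 0 became 1 with DESeq2 and 164 without a low-count filter, and lay between 0 and 6 with a library left out. Of the 7 lists called with genotype, 1 was called with an estimated correlation and 2 by fry. The range was 4 to 11 with a library left out, and a replicate block gave 8. Added after seeing the data, the test without Rapgef3 gave 4 lists and an estimated correlation without Epac1-PLN replicate 4 gave 2. Only the endothelial list changed direction with a call, without Epac1-PLN replicate 4 (adjusted p = 0.0260, with 0.888 the highest when a library was left out). Except where fewer samples or genes entered, the cause was not tested.

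Of 152 genes named by the rule, 26 were called with genotype, and 0 of these changed direction in any alternative. Rapgef3 (log2 fold change 6.82 to 7.11) and Cntn3 (5.71 to 7.65) were called in all 28 alternatives, and Hsd17b11 and Cdh22 in all but 1. Bves and Rabep2 were not called in 20 of 28, Cacna1g in 16, Lrp11 and Mov10 in 15, Dusp26 in 13, 4930529M08Rik in 12, Rp1 in 11 and Kcnv2 in 10. Among uncalled genes and lists, 50 and 43 values changed sign. The median of all tested genes stayed between -0.01 and 0.01, and that of the fatty acid oxidation genes between -0.30 and -0.17. Removing mitochondrially encoded genes moved nothing, since the table holds none. At these depths about 42.4% of simulated genes with a log2 fold change of 0.5 were called, so smaller changes can go unseen.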

Other observations

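Beyond the lists fixed beforehand, genes of peroxisomes and lipid droplets were looked up after the fall of the fatty acid oxidation genes had been seen. Of 21 measured genes 16 lay lower in Epac1-PLN cells, with a median log2 fold change of -0.12. Over all genes 1 fell, the lipid droplet coat gene Plin2 (-0.44 ± 0.07 SE, adjusted p = 0.0185, edgeR). Adjusted over this group alone 5 passed, among them Plin2, the peroxisomal oxidation enzymes Hsd17b4 (-0.26) and Ehhadh (-0.43), and the peroxisome assembly factor Pex19 (-0.19). The fat-handling genes Hsdl2 (-0.35, adjusted p = 0.0413, edgeR) and Ephx2 (-0.38, adjusted p = 0.0467, edgeR) fell too. The fatty acid transporter gene Slc27a4 rose (0.38, adjusted p = 0.0414, edgeR). These genes were chosen after their values were seen.

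Potassium channel genes outside the fixed list were also chosen after their values were seen. Of 7 measured, 2 rose over all genes, Kcnq5 (1.26) and Kcnc1 (1.07 ± 0.18 SE, adjusted p = 0.0209, edgeR). Adjusted over this group alone 5 passed, among them Kcna7 (0.20). Of 9 measured contactin, contactin-associated and cadherin genes other than Cntn3, 1 rose, Cdh22, with a group median of 0.01. Chromosome 6, which carries Cntn3, held 7 of the 81 called genes and 627 of the 12629 tested genes (Fisher's exact test, 2-sided, p = 0.123). The 7 include Cntn3 itself, for which this chromosome was chosen.

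Gm26924, a gene with ribosomal-RNA-like sequence, took 0.777% of counts in wildtype replicate 3, 0.650% in wildtype replicate 4 and 0.487% in Epac1-PLN replicate 4, against 0.0775% to 0.224% in the other libraries.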
